A study of Mus musculus with 6 samples.

How the data were processed

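Bulk RNA-seq had been made from total RNA of primary alveolar macrophages of allergen-exposed mice, with 3 wild-type and 3 Trim33 knockout libraries. Per the labels' protocols, RNA was extracted with TRIzol and libraries were prepared with an MGI kit. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and the mouse build GRCm38.p6, without saying which tool made which value. The program that estimated expression, its annotation and whether strand was used are not given in the sources used here. The authors deposited a table of TPM values and a table of FPKM values, both per gene and library and rounded to 2 decimals, per the file headers. TPM scales each gene by its length and each library to the same total, so a rise of abundant genes lowers all others, and depth is lost.

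Values were estimates and not whole reads, and no count table was used here. Low FPKM values were searched for steps that would give the relative depth of the libraries, among 1234 to 1324 genes between 0.2 and 1 FPKM in each comparison with wild-type replicate 1. No step was shared, since the most frequent ratio bin held 88 to 117 genes and its runner-up 88 to 117, so depth is unknown. No mitochondrially encoded gene was in the table. The table held 17142 genes identified by Entrez ID and symbol. Of these, 17024 (99.3%) matched the RefSeq annotation of GRCm38.p6, from which coordinates, gene types and the names of 24 genes whose symbols had been turned into dates were taken. By that annotation 98.2% were protein coding, so noncoding genes are little covered. A symbol carried by a pair of rows was kept apart by its ID. Whether a change lay in an exon, intron or UTR cannot be read from totals per gene.

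Groups were taken from the sample labels. All comparisons set the 3 knockout libraries against the 3 wild-type libraries with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a pseudocount of 1 and moderated variances with a trend and robust estimation. Genes with at least 1 TPM in at least 3 of 6 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11111 genes tested. A log2 difference is on the log2(TPM + 1) scale, which understates the change of low genes, and a fold given in the text is the ratio of mean TPM. Where 2 TPM values are joined without an error, they are the wild-type and knockout means of 3 libraries each. Trim33 was also compared with a two-sided exact permutation test. No 2 libraries were duplicates, since the highest share of genes with identical values in any pair was 0.369%.

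A collection of 39 gene lists for macrophage identity and activation, interferon, inflammation, metabolism, cell cycle, stress and other cell types had been fixed before the data were examined, as had the tests, the alternatives and the rule for named genes, except where stated. The 33 lists with at least 5 tested genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over lists, and again with the correlation estimated per list and with fry, which does not set a list against other genes. The rule named Trim33, then the 12 genes with the largest positive and the 12 with the largest negative log2 difference among called genes whose groups did not overlap, leaving out symbols without an established name and pseudogenes. For each described list it named up to 4 members with the smallest adjusted p, with Siglecf, Marco, Pparg, Car4 and Fabp4 for alveolar macrophages and Ifnb1, Irf7 and Isg15 for type I interferon. Genes outside this rule (Ccr2, Mertk, H2-Ab1, Ctsk, Mrc1, Thbs1, Smurf2, Scgb1a1, Macrod2 and Ddx3y, and, in the closing observations, Mylip, Trim24, Trim28, Cybb, S100a4, Clec4e and the neighbouring genes) were chosen after their values were seen. A result on a single gene is not reported here.

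Alternatives were the FPKM values, pseudocounts of 0.1 and 5, no filter, a minimum of 5 TPM, median-ratio scaling, quantile normalization, plain variance moderation, library weights, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. Added after the data were seen were a fit without wild-type replicate 1 and knockout replicate 3 together and lists without members shared with the interferon lists. The limma fit was tested on simulated data for this comparison, with 11111 genes. It recovered 85 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2, with 10 false calls among 190. Noise was drawn independently per gene without a shift between libraries, so this share of false calls need not hold for the real data. In the same simulation camera called 1 raised list and 0 of 30 unchanged ones, with genes drawn independently. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.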

Results

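Gene expression was measured by bulk RNA-seq in primary alveolar macrophages, the resident phagocytes of the lung airspaces, from mice exposed to an allergen. The 6 libraries fell into 2 groups of 3, wild type and Trim33 knockout. Trim33 encodes TIF1γ, a tripartite-motif protein that binds chromatin and SMAD proteins. The comparison asks which transcripts differ in alveolar macrophages that lack Trim33 after a single allergen challenge. Expression was read as TPM, a length-scaled share of the transcripts in a library that sums to 1000000 in each library, so the sequencing depth behind each value is unknown and no counting interval can be given. Each library had 15182 to 15535 genes above 0, and the 10 most abundant genes took between 17.8% and 19.5% of the TPM. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

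Trim33 itself (Entrez gene 94093, chromosome 3, 103279293 to 103358770 on GRCm38.p6) was lower in all 3 knockout libraries than in any wild-type library. Wild-type replicates 1, 2 and 3 had 6.83, 10.97 and 6.86 TPM, and knockout replicates 1, 2 and 3 had 2.63, 3.34 and 3.98 TPM. The means were 8.22 ± 2.38 TPM in wild type and 3.32 ± 0.675 TPM in knockout (SD, n = 3 each), so that 40.3% of the wild-type level remained. The log2 difference was -1.08 ± 0.19 (SE), with a limma adjusted p of 0.0114. The two-sided exact permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The values are totals over the gene, and the labels do not state which exons were deleted, so transcript from exons that remain in a knockout allele cannot be separated from intact transcript.

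Of 11111 genes tested, 497 were higher and 1129 lower in the knockout at an adjusted p under 0.05 (limma on log2(TPM + 1), n = 3 per group). The higher genes held the larger differences, with 173 higher genes but 39 lower genes changed by at least 2-fold. The 3 knockout values lay wholly above or below the 3 wild-type values for 44.4% of the tested genes. Chance gives 10% for a single gene, but genes that vary together can separate jointly. The median-ratio scaling factor was also lower in every knockout library than in any wild-type library, so a shift between libraries could separate many genes. The 44.4% is therefore no measure of a genotype effect. The median log2 difference over all tested genes was -0.15, and the changes below are to be read against that shift. Higher genes made up 30.6% of the calls on the TPM values, but 63.5% (665 higher, 383 lower) after median-ratio scaling, which moved the median to -0.0025, and 48.8% (559 higher, 587 lower) after quantile normalization. The counts also rested on single libraries. They were 800 higher and 2577 lower without wild-type replicate 1, 193 and 185 without wild-type replicate 2, and 124 and 84 without wild-type replicate 3. Leaving out knockout replicate 1, 2 or 3 gave 191 and 129, 168 and 141, or 441 and 559.

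**Figure D1:**
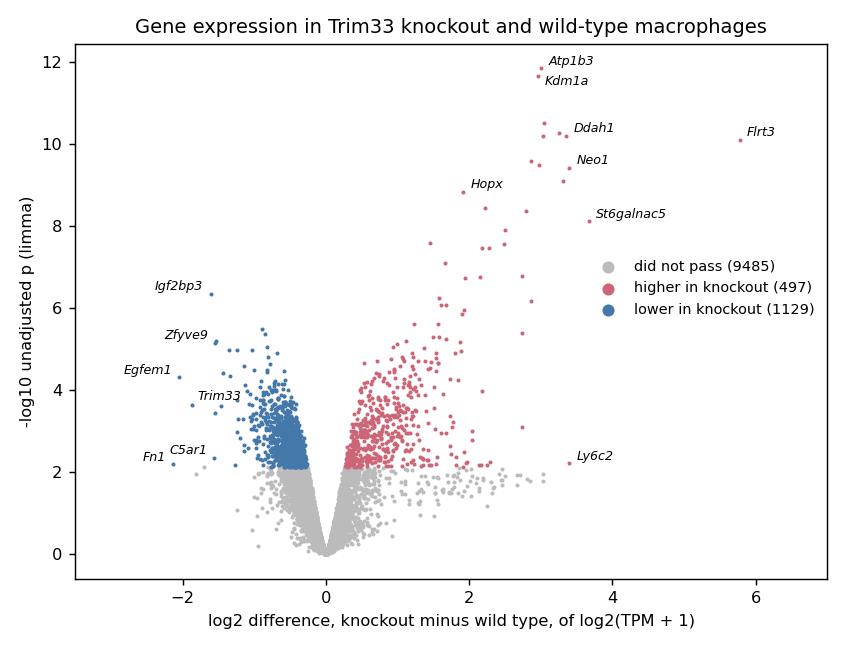
Log2 difference between Trim33 knockout and wild type (x axis, on the log2(TPM + 1) scale) against -log10 of the unadjusted limma p (y axis) for the 11111 genes tested, 1 point per gene. The 497 genes higher and 1129 genes lower at an adjusted p under 0.05 are coloured, and Flrt3 lies farthest to the right at 5.78.

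The largest rises were in genes that were low or nearly silent in wild type. Flrt3 (Entrez gene 71436, chromosome 2, 140658198 to 140671476), a leucine-rich-repeat adhesion protein of the cell surface, rose from 3.32 ± 0.502 to 239.9 ± 63.8 TPM (SD, n = 3 each), a log2 difference of 5.78 ± 0.17 (limma adjusted p 1.23e-07). Flrt3 lies within the span of Macrod2, which rose from 1.99 to 3.48 TPM, and reads of overlapping genes may not have been separable. Neo1 (chromosome 9, 58874679 to 59036614), which encodes the netrin and repulsive guidance molecule receptor neogenin, rose from 0.23 ± 0.12 to 11.9 ± 1.01 TPM. The sialyltransferase gene St6galnac5 was listed at 0, 0.05 and 0 TPM in wild type and at 7.93, 13.76 and 15.51 TPM in knockout. Dleu7 was listed at 0 in all 3 wild-type libraries and at 7.56, 9.53 and 9.76 TPM in knockout. Ddah1, which encodes an enzyme that breaks down asymmetric dimethylarginine, rose from 2.62 ± 0.133 to 36.1 ± 4.6 TPM.

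Other genes rose from an already measurable level to high abundance. Atp1b3 (Entrez gene 11933, chromosome 9, 96332655 to 96364431), a beta subunit of the sodium-potassium ATPase, rose 8.06-fold, from 395 ± 13.1 to 3187 ± 143 TPM, with a log2 difference of 3.01 ± 0.08 (limma adjusted p 1.20e-08). Kdm1a (Entrez gene 99982, chromosome 4, 136550533 to 136602787), the histone lysine demethylase LSD1, rose 8.02-fold, from 24.3 ± 0.881 to 194.7 ± 5.59 TPM. The scavenger receptor gene Colec12 rose from 52.5 ± 5.48 to 511 ± 77.9 TPM and the protease inhibitor gene Spink2 from 5.74 ± 0.586 to 54.4 ± 1.99 TPM. Zbtb8b, a zinc finger gene, rose from 14.8 ± 1.77 to 124 ± 19.3 TPM. Olfr1033, of the olfactory receptor family, rose from 71.9 ± 10.3 to 593 ± 58.1 TPM, and Ly6c2, a surface antigen of inflammatory monocytes, rose from 3.92 ± 2.15 to 55.6 ± 31.8 TPM. Olfr1033 and Ly6c2 have close paralogs, so their values are uncertain to the extent that reads were shared. The Ly6c2 call was lost without any 1 of wild-type replicates 2 and 3 and knockout replicates 1 and 2.

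Among the genes that fell, Fn1 (Entrez gene 14268, chromosome 1, 71585473 to 71653280), which encodes the matrix protein fibronectin, went from 429 ± 161 to 98.9 ± 40.8 TPM, a log2 difference of -2.13 ± 0.46 (limma adjusted p 0.0470). Its call was lost when any 1 library other than wild-type replicate 1 was left out. Egfem1 fell from 3.73 ± 1.89 to 0.07 ± 0.035 TPM and Marchf4, of a family of membrane-bound ubiquitin ligases, from 5.17 ± 3.14 to 0.56 ± 0.17 TPM. Igf2bp3, an RNA-binding protein, fell 4.36-fold, from 6.87 ± 0.775 to 1.57 ± 0.146 TPM. C5ar1, the receptor of the complement fragment C5a, fell from 82.7 ± 21.4 to 28.1 ± 10.2 TPM. Zfyve9, which encodes the SMAD anchor protein SARA, fell from 4.15 ± 0.995 to 0.75 ± 0.24 TPM, and the fatty acid binding protein gene Fabp1 from 134.5 ± 23.5 to 46.4 ± 15.2 TPM. Gprc5c, Klk8, Ptprs, Adcy4 and Acaa1b completed the 12 largest falls, with log2 differences from -1.53 for Gprc5c to -1.27 for Acaa1b. The C5ar1 and Fabp1 calls were lost without wild-type replicate 2 or 3 or knockout replicate 2, the Klk8 call without wild-type replicate 2 or 3 and the Marchf4 call without knockout replicate 2. Acaa1b, which has a close paralog in Acaa1a, did not pass after median-ratio scaling or when any 1 library other than knockout replicate 1 was left out.

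**Figure D2:**
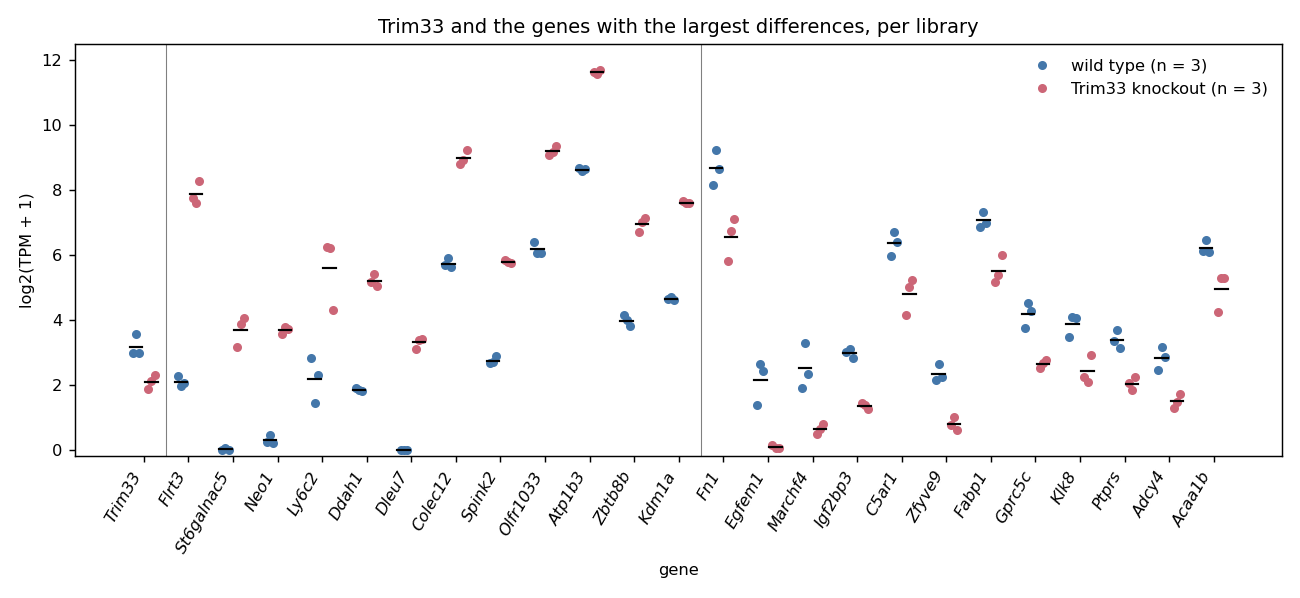
Log2(TPM + 1) (y axis) of Trim33, the 12 genes with the largest rises and the 12 with the largest falls (x axis), with 1 point per library, wild type in blue and Trim33 knockout in red, and a bar at each group mean of the log2 values. Groups that do not overlap were a condition for showing a gene other than Trim33, whose groups do not overlap either. Kdm1a went from 24.3 to 194.7 TPM with little spread in either group.

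Genes of the type I interferon response shared a direction in the knockout, although most did not pass singly over all genes. All 32 tested members of the list had a positive difference, with a median of 1.82 on the log2 scale, and 14 of the 32 passed over all genes tested (32 when adjusted over the list alone) with none lower. Among them, the cytosolic RNA sensor gene Ddx58 rose from 43.0 ± 7.97 to 84.4 ± 14.7 TPM, Trim30a from 55.5 ± 9.96 to 100.2 ± 14.9 TPM, Parp14 from 24.9 ± 4.27 to 43.7 ± 6.30 TPM and Ifih1, another RNA sensor, from 32.98 ± 5.86 to 55.0 ± 7.36 TPM. Irf7, the transcription factor that amplifies interferon production, had 172 ± 115 TPM in wild type and 842 ± 323 TPM in knockout and did not pass (limma adjusted p 0.0796), nor did the ubiquitin-like protein gene Isg15, at 53.04 ± 44.2 and 282 ± 112 TPM (adjusted p 0.0811). Ifnb1, the interferon-β gene, was under the filter, at 0.12, 0.13 and 0 TPM in wild type and 0.24, 0.37 and 0.49 TPM in knockout. The spread within groups was wide, since the mean log2 value of the list was 5.63, 4.30 and 4.94 in wild-type replicates 1, 2 and 3 and 7.06, 6.89 and 6.16 in knockout replicates 1, 2 and 3. The list passed the camera test (adjusted p 6.47e-30) but not with an estimated correlation (adjusted p = 0.253). Without wild-type replicate 1, 2 or 3, 29, 5 or 0 members passed, and without knockout replicate 1, 2 or 3, 4, 2 or 12 passed, while the median stayed between 1.44 and 2.13.

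In the interferon-gamma response list, 10 of 26 members were higher and none lower (19 higher and 1 lower when adjusted over the list alone). Its median was 1.07, with 23 of 26 differences positive. Socs1, a feedback inhibitor of cytokine signalling, rose from 5.06 ± 1.09 to 15.9 ± 5.62 TPM, the immunity-related GTPase genes Irgm2 and Igtp from 10.9 to 24.1 and from 26.3 to 62.4 TPM, and the guanylate-binding protein gene Gbp7 from 21.4 to 32.5 TPM. These GTPase genes belong to families of close paralogs. The list passed camera (adjusted p 1.34e-14) but not with an estimated correlation (adjusted p = 0.278). Its count of higher members ran from 0 without wild-type replicate 2 or 3 or knockout replicate 2 to 17 without knockout replicate 3. In the list of MHC class II presentation, 3 of 14 members were higher and none lower (10 higher when adjusted over the list alone). They were H2-DMb1, a chaperone of peptide loading, which rose from 142 to 193 TPM, and the costimulatory receptor and ligand genes Cd40, from 0.613 to 4.71 TPM, and Cd80, from 19.1 to 26.3 TPM. The class II chain gene H2-Ab1 had 132.7 ± 60.4 TPM in wild type and 464 ± 286 TPM in knockout and did not pass (adjusted p 0.103). The list passed camera (adjusted p 1.95e-07) but not with an estimated correlation (adjusted p = 0.182), and its higher members numbered from 0 without wild-type replicate 2 or 3 or knockout replicate 2 to 5 without wild-type replicate 1.

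Markers of monocytes and monocyte-derived macrophages mostly had positive differences, 19 of 24, with a median of 0.61. Of the 24 members, 7 passed as higher and 2 as lower (15 higher and 2 lower when adjusted over the list alone). Besides Ly6c2, Gpnmb rose from 717 ± 50.4 to 1016 ± 74.96 TPM, the apolipoprotein gene Apoe from 51.7 ± 7.95 to 127 ± 35.4 TPM, Plac8 from 3.20 ± 0.569 to 29.9 ± 14.7 TPM and the proteoglycan gene Vcan from 0.673 to 2.32 TPM, while Fn1 and the phagocytic receptor gene Mertk (185 to 133 TPM) fell. Ccr2, the chemokine receptor of inflammatory monocytes, had 4.83 ± 0.946 TPM in wild type and 4.50 ± 1.65 TPM in knockout. The list passed camera (adjusted p 1.56e-10) but not with an estimated correlation (adjusted p = 0.169), and its higher members numbered from 0 without wild-type replicate 3 to 11 without knockout replicate 3.

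Of 30 alveolar macrophage identity genes, 11 were lower on the TPM scale, 1 was higher and 18 did not pass (12 lower and 3 higher when adjusted over the list alone). Siglecf, the sialic-acid-binding lectin used to identify these cells, fell from 382 ± 46.4 to 272 ± 9.35 TPM. The cholesterol exporter gene Abcg1 fell from 617 ± 67.4 to 407 ± 23.9 TPM, Ear1 from 2166 ± 94.6 to 1274 ± 186 TPM and Ear2 from 4257 ± 527 to 2737 ± 232 TPM, and Ear1 and Ear2 are near-identical ribonuclease genes whose reads may have been shared. The cysteine protease gene Ctsk rose from 1536 to 2080 TPM. The transcription factor gene Pparg (307 and 265 TPM), the scavenger receptor gene Marco (973 and 751 TPM), Fabp4 (403 and 317 TPM) and Car4 (1481 and 2193 TPM) did not pass, with adjusted p of 0.155, 0.277, 0.161 and 0.0750. The list did not pass camera (adjusted p 0.0911). After median-ratio scaling 5 members were lower and 2 higher, and Ear2 and Chil3 no longer passed. The lower members numbered from 4 without wild-type replicate 2 or 3 or knockout replicate 2 to 11 without wild-type replicate 1. No member, Ctsk included, was higher when any 1 library other than wild-type replicate 1 was left out, and 2 were higher without that library.

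Of 37 genes of the G2 and M phases of the cell cycle, 12 were lower, none was higher and 25 did not pass (21 lower when adjusted over the list alone). The cytokinesis genes Anln and Kif23 fell from 46.5 ± 5.22 to 30.02 ± 3.46 TPM and from 77.8 ± 9.92 to 52.7 ± 4.26 TPM, and the mitotic motor gene Kif11 from 35.9 ± 5.17 to 25.4 ± 1.66 TPM. The list passed camera as lower (adjusted p 0.0012) but not with an estimated correlation (adjusted p = 0.642). The camera call ended without wild-type replicate 1, 3 members were lower after median-ratio scaling, and the lower members numbered from 1 without wild-type replicate 3 or knockout replicate 1 to 12 without wild-type replicate 1. Of 35 genes of the S phase, 2 were higher, none was lower and 33 did not pass (1 higher when adjusted over the list alone). With 1 library left out, 1 to 8 were higher, the most without wild-type replicate 1. Among these S phase genes, the chromatin assembly gene Chaf1b rose from 33.2 to 44.7 TPM. The S phase list passed camera as higher (adjusted p 0.0155, median 0.04) but not with an estimated correlation (adjusted p = 0.700), nor without the filter or without wild-type replicate 2 or 3.

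**Figure D3:**
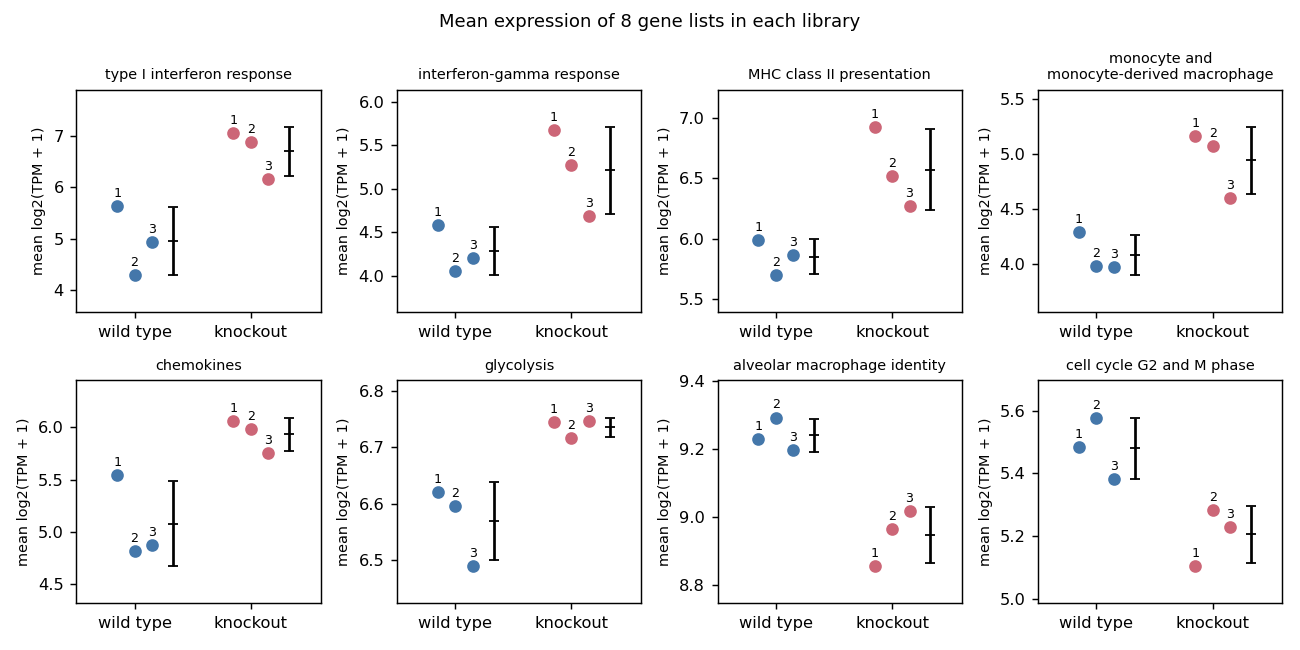
Mean log2(TPM + 1) over the tested members of 8 gene lists (y axes, each with its own range that does not start at 0) in each library, with points numbered by replicate, wild type in blue and Trim33 knockout in red, and the group mean with its SD (n = 3) in black. Wild-type replicate 1 has the highest wild-type value of the type I interferon list, at 5.63, and knockout replicate 3 the lowest knockout value, at 6.16.

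Of 23 chemokines, 4 were higher and 1 lower (5 and 1 when adjusted over the list alone), with the monocyte attractant genes Ccl2 rising from 24.4 ± 9.09 to 111 ± 20.5 TPM, Ccl7 from 4.19 ± 1.11 to 12.9 ± 3.21 TPM and Ccl12 from 1.30 to 5.26 TPM, while Cx3cl1 fell from 40.0 to 23.9 TPM. Of 21 inflammatory cytokines and mediators, 5 were higher and 2 lower (7 and 2 when adjusted over the list alone). The siderophore-binding protein gene Lcn2 rose from 6.44 ± 2.08 to 16.0 ± 1.92 TPM, the cyclooxygenase gene Ptgs2 from 7.53 to 14.1 TPM, Tnfsf9 from 2.61 to 6.89 TPM and the macrophage growth factor gene Csf1 from 2.96 to 7.77 TPM. Of 30 genes of the NF-κB pathway and inflammasomes, 10 were higher and 1 lower (11 and 1 when adjusted over the list alone), among them Nfkbie (8.60 to 20.9 TPM), an inhibitor of NF-κB, Casp4 (51.7 to 91.6 TPM), the protease of the noncanonical inflammasome, Nfkb2 (29.2 to 39.8 TPM) and Traf1 (1.203 to 3.69 TPM). These lists passed camera with adjusted p of 1.21e-09, 1.96e-06 and 2.00e-07, but not with an estimated correlation (adjusted p = 0.182, 0.169 and 0.169). Without wild-type replicate 1 the higher members numbered 10, 8 and 13 in these lists. They numbered 2 for chemokines without wild-type replicate 2 or 3, 1 for the inflammatory list without wild-type replicate 3 or knockout replicate 2, and 1 for the NF-κB list without wild-type replicate 3.

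In glycolysis 7 of 22 members were higher and 2 lower (11 and 3 when adjusted over the list alone), with the glucose transporter gene Slc2a1 rising from 37.0 ± 10.9 to 70.4 ± 2.15 TPM, Pkm from 675 to 927 TPM and Eno1 from 752 to 1115 TPM, and Pfkfb4 falling from 108 to 72.2 TPM. Among metalloproteinases and matrix genes 7 of 22 were higher and 1, Fn1, lower (8 and 2 when adjusted over the list alone). The metalloproteinase gene Mmp14 rose from 56.0 ± 13.6 to 127 ± 20.6 TPM, the metalloproteinase inhibitor gene Timp1 from 2.69 to 9.36 TPM, the urokinase gene Plau from 17.7 to 29.1 TPM and the galectin gene Lgals3 from 2420 to 3579 TPM. In the lysosome list 7 of 36 were higher and 1 lower (7 and 2 when adjusted over the list alone). Its median was 0.02, with 19 of 36 differences positive. Its mean of 0.054 was 0.15 above that of other genes, against which camera sets it. Rises included the membrane proteins Cd63 (667 to 1273 TPM) and Cd68 (2599 to 3417 TPM) and the cathepsins Ctsz (1949 to 2795 TPM) and Ctsb (2726 to 3777 TPM). In the complement list 3 of 20 were higher and 2 lower (11 and 2 when adjusted over the list alone). The C3a receptor gene C3ar1 rose from 1.74 to 5.57 TPM, the protease gene C1ra from 63.6 to 100.1 TPM and C4b from 1.98 to 4.95 TPM, whereas the C5a receptor genes C5ar1 and C5ar2 (11.4 to 4.33 TPM) fell. These 4 lists passed camera, with adjusted p of 8.99e-06, 0.000243, 0.0035 and 4.04e-06, but not with an estimated correlation (adjusted p = 0.169, 0.262, 0.278 and 0.278). The lysosome call ended after quantile normalization, where 2 members were higher. Higher members numbered 1 for glycolysis without wild-type replicate 2 or 3 or knockout replicate 1 or 2, 1 for matrix genes without wild-type replicate 2, 1 for lysosomes without wild-type replicate 2 or knockout replicate 1 or 2, and 0 for complement without wild-type replicate 3. At most they numbered 11 for glycolysis, 8 for matrix genes and 7 for lysosomes, each without wild-type replicate 1, and 7 for complement without knockout replicate 3.

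Targets of TGF-β and SMAD proteins went both ways, with 3 of 23 members higher and 3 lower (3 and 5 when adjusted over the list alone). Id3, an inhibitor of helix-loop-helix transcription factors, rose from 26.6 ± 3.94 to 81.8 ± 18.2 TPM, Tgif1, a SMAD corepressor, from 73.7 to 113.0 TPM, and the TGF-β activator gene Thbs1 from 3.15 to 7.52 TPM. The receptor gene Tgfbr1 fell from 87.5 ± 17.1 to 50.4 ± 2.77 TPM, Klf10 from 93.2 to 54.6 TPM and the ubiquitin ligase gene Smurf2 from 21.2 to 15.4 TPM. The list did not pass camera (adjusted p 0.172), and its median of -0.03 was 0.12 after median-ratio scaling and 0.0017 after quantile normalization. Without knockout replicate 2, 1 member was higher and 2 were lower, and without wild-type replicate 1, 4 were higher and 7 lower. In the alternative activation list 3 of 25 members were higher and 7 lower (4 and 8 when adjusted over the list alone). The lectin-like gene Chil3 fell from 18104 ± 993 to 12585 ± 1734 TPM, Igf1 from 14.1 to 8.22 TPM and the mannose receptor gene Mrc1 from 554 to 348 TPM, while Socs3 rose from 35.4 ± 4.92 to 71.6 ± 7.88 TPM and Fcgr2b from 249 ± 4.23 to 360 ± 0.950 TPM. Chil3 has close paralogs and did not pass after median-ratio scaling. This list did not pass camera either (adjusted p 0.0585), which pointed up, as did its median of 0.12. Its lower members numbered from 0 without knockout replicate 2 to 7 without wild-type replicate 1.

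**Figure D4:**
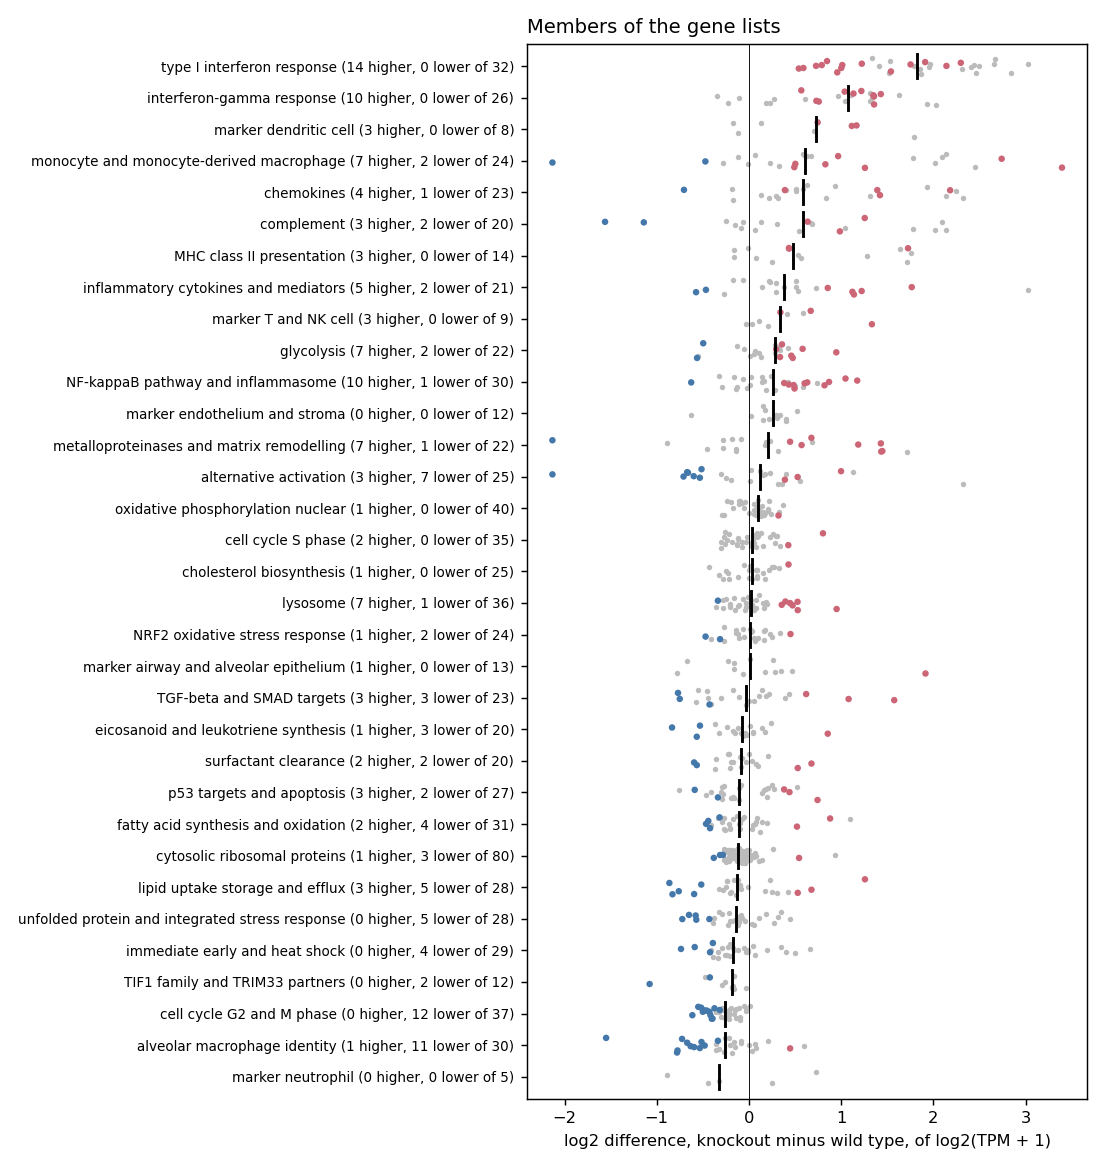
Log2 difference between Trim33 knockout and wild type (x axis, on the log2(TPM + 1) scale) of the members of the 33 tested gene lists (y axis), 1 point per gene, with red and blue for genes higher or lower at an adjusted p under 0.05, grey for the others and a black bar at the median of each list. The type I interferon list has the highest median, 1.82, with all 32 members above 0, and some medians near 0, such as that of the TGF-β list, change sign with the scaling between libraries.

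Markers of other cell types that such a preparation could hold were read in the same libraries. Dendritic cell markers had 3 of 8 higher and none lower (5 higher when adjusted over the list alone), namely the chemokine receptor gene Ccr7 (1.65 to 4.93 TPM), Fscn1 (0.893 to 3.28 TPM) and Cacnb3 (0.83 to 2.10 TPM). The dendritic cell markers Flt3, Zbtb46, Xcr1 and Siglech were under the filter, at most 1.03 TPM in any library of either group. T and NK cell markers had 3 of 9 higher (4 when adjusted over the list alone), which were Il7r (4.73 to 12.9 TPM), Gzma (2.31 to 4.21 TPM) and Cd2, which was abundant in both groups (569 to 719 TPM). Of 6 mast cell and basophil markers present, 2 were tested and both were higher, with Tpsb2 at 0, 0 and 0.09 TPM in wild type and 2.99, 2.38 and 1.61 TPM in knockout, and Hdc rising from 1.41 to 3.66 TPM. The others, Cpa3, Cma1, Ms4a2 and Mcpt4, were under the filter, at most 0.28 TPM in any library of either group. Among 13 epithelial markers 1, the homeodomain gene Hopx, was higher, from 24.8 ± 2.66 to 95.8 ± 3.41 TPM, while Scgb1a1, the secretory product of club cells, had 108 ± 14.8 and 101.2 ± 44.0 TPM and Sftpc, the surfactant gene of type 2 cells, 67.8 ± 16.6 and 44.7 ± 18.7 TPM. The plasma cell gene Jchain was lower, from 3.47 to 1.36 TPM, as 1 of 3 B and plasma cell markers tested. No tested marker of neutrophils (5), eosinophils (2), endothelium and stroma (12) or erythrocytes (3) passed over all genes, and after median-ratio scaling 2 of the 12 stromal markers, Acta2 and Dcn, did. Some passed in other alternatives. Without wild-type replicate 1, 2 neutrophil markers were higher and 1 lower, 1 eosinophil marker was higher and 1 stromal marker was lower. After quantile normalization, and without wild-type replicate 2, 2 stromal markers were higher. Camera called the dendritic, T and NK, stromal and epithelial lists higher (adjusted p 5.40e-05, 9.29e-05, 0.0078 and 0.0253), and none with an estimated correlation (adjusted p = 0.222, 0.169, 0.623 and 0.494). Ddx3y, from the Y chromosome, was at most 0.06 TPM in any library. The epithelial call ended after either scaling, with FPKM, without the filter and without knockout replicate 2, and the stromal call ended after median-ratio scaling and without wild-type replicate 1 or 3. At least 1 dendritic cell marker passed whichever library was left out, whereas 0 T and NK cell markers passed without any 1 of the knockout libraries.

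In all, camera with its preset correlation called 18 lists higher and 1 lower of 33 tested, and with a correlation estimated per list it called 0 (smallest adjusted p = 0.169). The self-contained fry test also called 0 lists for a shift to either side, while its mixed test called 27. Other groupings of the same 6 libraries gave up to 21 camera calls.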

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

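The fit without wild-type replicate 1 and knockout replicate 3 together and the lists without shared interferon genes were chosen after the data were seen, and fry values were set to list means after first results had been seen, since fry does not compare a list with other genes. Trim33 was lower with an adjusted p under 0.05 in all 17 alternatives run for genes. None of the 24 largest differences changed sign in any alternative that tested them, and 18 to 24 of them kept their call (20 were tested with a minimum of 5 TPM and 23 with FPKM). The count of higher genes was 519 with FPKM, 490 and 479 with pseudocounts of 0.1 and 5, 348 without a filter, 405 with a minimum of 5 TPM, 665 and 559 with the scalings and 469 with plain moderation. The count of lower genes was 816 with FPKM and 1169 with a minimum of 5 TPM, but 326 without a filter, 383 with median-ratio scaling, 587 with quantile normalization and 672 with plain moderation. Of the 383 lower genes after median-ratio scaling all 383 were among the 1129, and 451 of the 665 higher genes were among the 497. At least a 2-fold change left 173 higher and 39 lower genes, fewer by construction. Library weights gave 1004 and 2552, and the fit without wild-type replicate 1 and knockout replicate 3 gave 777 and 1984. Leaving out 1 library gave 124 to 800 higher and 84 to 2577 lower genes, with the extremes without wild-type replicates 3 and 1, and a smaller group lowers the power by construction. The cause of the other shifts was not tested.

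Whether the replicate numbers pair the libraries could not be settled from the values. Deviations from the group means correlated at 0.32, -0.033 and 0.085 between libraries numbered 1, 2 and 3. The 0.32 was the highest between any wild-type and any knockout library, but knockout replicate 3 correlated best with wild-type replicate 2 (0.30). With the replicate number as a block, 753 genes were higher and 2147 lower, 19 lists higher and 1 lower, and Trim33 remained lower.

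Lists called higher numbered 16 to 19 in all alternatives except the estimated correlation and fry, where 0 were called higher and 0 lower. Lists called lower numbered 3 with a pseudocount of 5, 2 without a filter, 3 with quantile normalization, 2 with library weights, 0 without wild-type replicate 1 and knockout replicate 3 together, 1 without shared interferon genes, and 0 to 2 when 1 library was left out, 0 without wild-type replicate 1. Values below are mean log2 differences of list members minus those of other genes, or list means for fry. Cholesterol biosynthesis, called higher in the main comparison, turned to -0.0049 with library weights and -0.054 without wild-type replicate 1 and knockout replicate 3, and ranged from -0.015 to 0.21 with 1 library left out. The lists that changed sign and had not been called were near 0. Ribosomal proteins turned to 0.0051 with FPKM, 0.0011 with a pseudocount of 0.1, 0.0059 with a minimum of 5 TPM and 0.012 with median-ratio scaling. Lipid uptake turned to -0.0072 with a pseudocount of 5, -0.016 without a filter, -0.042 with quantile normalization and -0.081 with fry. Surfactant clearance turned to -0.037 without a filter, -0.047 with quantile normalization and -0.079 with fry. Eicosanoid synthesis turned to 0.00061 with median-ratio scaling, 0.055 with library weights and 0.0035 without wild-type replicate 1 and knockout replicate 3, where the unfolded protein list turned to 0.0078. Fry gave -0.0091 for TGF-β targets, -0.051 for fatty acid genes, -0.013 for NRF2 genes and -0.049 for p53 targets. Neutrophil markers turned to 0.16 without a filter, where 14 members in place of 5 were tested and the list was called higher. With 1 library left out, the ranges were -0.11 to 0.10 for ribosomal proteins, called higher without wild-type replicate 3 and lower without wild-type replicate 2, -0.056 to 0.028 for eicosanoid synthesis, -0.0031 to 0.086 for fatty acid genes, -0.087 to 0.048 for immediate early genes, -0.0097 to 0.041 for lipid uptake, -0.084 to 0.015 for neutrophil markers and -0.0046 to 0.052 for surfactant clearance. The cause was not tested. Depth is unknown, so how far low genes are limited by counting cannot be given.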

Other observations

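The tests of monocyte transcripts and of neighbouring genes were chosen after part of the results had been seen. In the unfolded protein and integrated stress response list 5 of 28 members were lower and none higher (8 lower and 1 higher when adjusted over the list alone), with the transcription factor gene Atf5 falling from 47.5 ± 7.01 to 28.2 ± 1.32 TPM (SD, n = 3 each), the chaperone gene Dnajb9 from 134 ± 11.6 to 89.99 ± 3.29 TPM and Herpud1, of endoplasmic reticulum degradation, from 86.9 to 54.7 TPM. Its median of -0.14 was 0.02 after median-ratio scaling, where 2 members were lower and Herpud1 did not pass, and camera did not call it (adjusted p 0.758). Lipid uptake, storage and efflux genes went both ways (3 higher and 5 lower of 28, also when adjusted over the list alone). Besides Apoe, the scavenger receptor gene Msr1 rose from 59.7 to 96.4 TPM, while Abcg1, the triglyceride synthesis gene Dgat1 (60.1 to 32.5 TPM) and Mylip, which degrades lipoprotein receptors (19.9 to 10.5 TPM), fell. Fatty acid genes had 2 of 31 higher and 4 lower (3 and 4 when adjusted over the list alone), the desaturase gene Fads2 rising from 1.77 to 4.13 TPM and the β-oxidation genes Hadhb, Ech1 and Cpt1a falling, though none of these 3 passed after median-ratio scaling. In the surfactant clearance list 2 of 20 were higher and 2 lower, among them the phospholipase gene Pla2g15 (259.5 to 174.2 TPM). Eicosanoid genes had 1 of 20 higher, Ptgs2, and 3 lower (1 and 4 when adjusted over the list alone), including the leukotriene hydrolase gene Lta4h (122.6 to 84.4 TPM) and the prostaglandin receptor gene Ptger2 (13.4 to 6.86 TPM). Camera called none of these lists (adjusted p from 0.524 to 0.819), and the medians of the lipid, fatty acid, surfactant and eicosanoid lists changed sign after median-ratio scaling. With 1 library left out, the lower members ran from 2 to 6 in the unfolded protein list, 2 to 9 in the lipid list, 0 to 7 in the fatty acid list, 1 to 3 in the surfactant list and 1 to 5 in the eicosanoid list, and the higher members from 0 to 1, 1 to 6, 0 to 3, 1 to 2 and 0 to 1, each with the most without wild-type replicate 1.

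Camera called the oxidative phosphorylation list higher (adjusted p 0.000102, median 0.10) with 1 of 40 members, Cox5b, higher (0 when adjusted over the list alone), and the cholesterol biosynthesis list higher (adjusted p 0.0253, median 0.03) with 1 of 25 members, Fdps, higher (1 when adjusted over the list alone), and neither with an estimated correlation (adjusted p = 0.468 and 0.700). Higher oxidative phosphorylation members numbered 6 without wild-type replicate 1 and 0 without any 1 of the other libraries, after quantile normalization, without the filter or with plain moderation. The cholesterol call ended without the filter and without wild-type replicate 1 or knockout replicate 3. The p53 and apoptosis list had 3 of 27 higher and 2 lower (4 and 4 when adjusted over the list alone), with the proapoptotic gene Bcl2l11 rising from 21.5 to 36.2 TPM, and with 1 library left out 0 to 6 were higher and 0 to 5 lower. The NRF2 list had 1 of 24 higher, Hmox1, and 2 lower, Cat and Taldo1 (also when adjusted over the list alone), of which Cat and Taldo1 did not pass after median-ratio scaling, 0 members passed either way without wild-type replicate 2 or 3 or knockout replicate 1 or 2, and 4 were higher and 2 lower without wild-type replicate 1. The immediate early and heat shock list had 0 of 29 higher and 4 lower (3 lower when adjusted over the list alone), namely Btg2, Fosb, Fos and Jun, of which Fosb, Fos and Jun did not pass after median-ratio scaling, and 0 to 6 members were lower with 1 library left out. Ribosomal protein genes had 1 of 80 higher, Rpl3l, and 3 lower (0 of either when adjusted over the list alone), but 37 lower with library weights, 0 lower after median-ratio scaling and, with 1 library left out, from 0 to 11 lower, the most without wild-type replicate 1. Among TIF1 family genes and partners of TRIM33, Trim33 and the nucleosome remodeller gene Chd4 (95.4 to 70.5 TPM) were lower of 12 (3 lower when adjusted over the list alone), while Trim24 (6.20 and 5.43 TPM), Trim28 (72.55 and 64.0 TPM) and Smad4 (24.9 and 20.6 TPM) did not pass. The Chd4 call was lost after median-ratio scaling, without the filter, with plain moderation and without wild-type replicate 2 or 3 or knockout replicate 1 or 2. Camera called none of these 5 lists (adjusted p from 0.0585 to 0.913).

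Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the comparison of genotypes, the real one, with 1626 genes against 0 in the highest of the others. For lists, 2 of the 10 splits gave as many, with 19 in the real split and 21 in the highest other, wild-type replicate 1 with knockout replicates 2 and 3 against the rest. With 10 splits a share under 0.05 cannot be reached. Each other split also mixed genotypes in both groups, so any genotype difference widened the spread within them. Their 0 genes are therefore no measure of calls by chance.

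The higher interferon response genes might rest on a single library or on more monocytes in the knockout preparations. Against a single library, the lowest median log2 difference of the type I list with 1 library left out was 1.44, without wild-type replicate 2, against 1.82 with all, although the number of members past the threshold went from 29 without wild-type replicate 1 to 0 without wild-type replicate 3. Monocytes stay open: the median of 17 tested monocyte transcripts outside the interferon lists was 0.61, under 0.909, which is 0.5 of the interferon median, but their upper quartile of 0.951 reached past it. Whether interferon raises some of the 17 was not tested. Some, such as Cybb and Fn1 (429 TPM), were already abundant in wild type, where added monocytes might raise them little. Their median is therefore a weak measure of monocytes. Ccr2 (4.83 to 4.50 TPM) and the abundant Cybb (1217 to 1170 TPM) were not higher and Fn1 fell, while S100a4 (26.9 to 63.7 TPM) and Clec4e (39.1 to 79.3 TPM) rose. A response of the macrophages themselves to the loss of Trim33 remains a hypothesis that these data cannot separate from a changed cell mix.

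Genes higher in the knockout lay next to each other on the chromosomes more often than random sets of tested genes. Among 494 higher genes with a position, 36 pairs of unlike-named neighbours within 100000 bp were both higher, where 15.6 were expected (permutation p = 0.0001, the smallest that 10000 draws can give). Unlike-named means only that the symbols start differently. The 36 pairs still held members of shared families, such as Igtp and Irgm2, so the count cannot set gene families or shared paralog reads aside. Overlapping annotations do not account for all of it, with 49 pairs of non-overlapping neighbours, like-named ones included, against 14.6 expected (permutation p = 0.0001). Pairs both unlike-named and non-overlapping numbered 30, against 13.8 expected (permutation p = 0.0003). DNA carried along with the targeted locus does not account for it, since 0% of the 65 genes in the unlike-named pairs lay on chromosome 3. Lower genes clustered too (119 pairs against 81.5), but 0.3% of equal-sized draws of them reached 36 pairs, and among 170 higher genes that did not follow the interferon list within groups 9 pairs were seen against 1.84 expected (permutation p = 0.0002). No biological explanation was tested, since neither TRIM33 binding nor repeats near these genes were analysed here, and an example is the run Fhod1, Slc9a5, Plekhg4, Kctd19, Tppp3, Zdhhc1 and Hsd11b2 on chromosome 8 (105329160 to 105523988 on GRCm38.p6), where log2 differences ran from 0.45 for Zdhhc1 to 1.604 for Tppp3 and some spans overlap, so that reads running from a gene into the next remain possible.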
